A study of Mus musculus with 20 samples.

How the data were processed

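Single nuclei were profiled from the preoptic area, the front part of the hypothalamus, of 20 adult C57BL/6J mice. The mice formed 4 groups of 5: females and males that breathed oxygen, and females and males that breathed isoflurane in oxygen. Per the labels' protocols, brains were flash frozen after cervical dislocation, the preoptic area was dissected from the frozen tissue, and nuclei were captured with the 10x Genomics 3′ kit at a target of 10000 nuclei and 20000 reads per nucleus. Group, sex and replicate number came from the sample titles, and each library came from a separate mouse. A mouse is named here by gas, sex and replicate number. The labels named no sequencing or dissection batch, so no batch was tested.

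The authors deposited raw counts of unique molecular identifiers (UMIs) per gene and nucleus, not normalized, with 26467 gene symbols. Per the submitters' processing notes, these counts were made with Cell Ranger on the mm10 build; its version and whether intronic reads or strand were used are not given in the sources used here. The authors split the nuclei of each mouse into inhibitory, excitatory and non-neuronal matrices, which made 60 matrices, and this deposited split defined the 3 classes. How the authors filtered nuclei or removed doublets is not given in the sources used here. Of 150250 deposited nuclei, 38 entries were left out because 19 barcodes stood in 2 matrices of a mouse, which left 150212. No further filter was applied to nuclei: the lowest number of genes detected in a nucleus was 501. No pair of libraries of a group agreed within sampling noise over 40 pairs, with a lowest chi-square per degree of freedom of 3.90.

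Library totals ran from 15611543 to 37022498 UMIs and from 4412 to 11095 nuclei per mouse. Summed per mouse, a class held 11084472 to 26625491 UMIs of inhibitory nuclei, 2945221 to 7676781 of excitatory nuclei and 884634 to 4528071 of non-neuronal nuclei, so genes of low level were measured least precisely in the non-neuronal class. CPM, the depth-scaled level of a gene, was computed here from the deposited counts with TMM library sizes.

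The mouse was the unit of every test. Counts of a class were summed per mouse and tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, robust, filterByExpr by group, TMM), with the 4 groups as the design. The isoflurane effect was the mean over both sexes of isoflurane minus oxygen, the interaction was the effect in females minus that in males, and the sex difference was oxygen females minus oxygen males. P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and every p was two-sided. The difference of the isoflurane effect between inhibitory and excitatory nuclei was tested with limma 3.58.1 on each mouse's difference of log2 CPM, with a prior count of 2. Other tools and settings were DESeq2 1.42.0, other normalization factors, no filter or a stricter one, an additive model, a depth covariate, equal nuclei per mouse and leaving out each mouse in turn.

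Before the data were examined, the mapping of samples, the tests, the alternatives to be tried, 33 gene lists, the cell type markers and the rule for naming genes were fixed. The lists held rapid response genes and a core of 13 of them, delayed response, MAPK feedback, glucocorticoid response, heat shock, cold-inducible, unfolded protein response and circadian clock genes. They also held GABA-A and glycine receptor subunits, a group of two-pore potassium, HCN and GIRK channels, ionotropic glutamate receptors, presynaptic release machinery, NRF2 and oxidative stress, hypoxia and glycolysis, cholesterol synthesis, preoptic neuropeptides, sleep-state and arousal receptors, sex-steroid signalling, sex chromosome and X escape genes. The rest held mitochondrially encoded genes, ribosomal proteins, nuclear oxidative phosphorylation, RNA of oligodendrocytes, astrocytes, microglia, vascular cells, ependymal and choroid plexus cells, neurons, excitatory neurons and inhibitory neurons, and genes of activated microglia and cytokines. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the lists of a class. Gene calls within a list are also given adjusted over the list alone.

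For each class and the isoflurane effect, the text names genes past the threshold with a mean of at least 5 CPM in either gas: the 8 with the largest positive and the 8 with the largest negative log2 fold change. The core list is given in full, with up to 4 called members of each other list. For the other contrasts and for cell types the number is 5 per direction, and for clusters it is the 6 with the smallest p. Genes named outside this rule are said to have been chosen after their values were seen.

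Nuclei of each class were clustered with scanpy 1.11.5 and leidenalg 0.10.2 on 30 components of 2000 variable genes ranked within libraries, with 20 neighbours, a resolution of 1 for neurons and 0.5 for non-neuronal nuclei, and seed 1. The 295 response, sex-linked, mitochondrial and ribosomal genes of the fixed lists were barred from clustering, so that they did not shape the clusters. Other genes that respond could still do so, which was not tested. The clustering gave 40 inhibitory, 37 excitatory and 19 non-neuronal clusters. A cluster was called like a type when at least 3 fixed markers were found in at least 10% of its nuclei and at least 2 times as high as in the rest of its class; this factor was lowered from 4 after the data were seen. Leading genes of a cluster were those of the largest fold over its class among genes found in at least 25% of its nuclei. The names rest on these markers and may differ from the authors' own.

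The core level of a cluster was the summed CPM of the 13 core genes in each mouse, over plain UMI totals without TMM, compared as log2(value + 1), with the differences of the 2 sexes averaged. Mice with at least 10 nuclei entered, and a cluster was tested with at least 4 such mice in each group, or 3 for the core level of named types. Treatment labels were permuted within each sex in an exact permutation test of up to 63504 arrangements, and p was adjusted over the 62 clusters tested. Whether the effect differs between neuronal clusters was tested after the data were seen, in all 45 clusters with at least 10 nuclei in each mouse. Each mouse was centred over the clusters, and the sum of squared effects, each over its permutation SD, was compared with the same permutations. Shares of nuclei with a core UMI were computed after thinning every nucleus to 1000 UMIs, leaving out shallower nuclei: from 0.936% to 1.54% of a group for inhibitory, 0.804% to 1.89% for excitatory and 10.8% to 15.1% for non-neuronal nuclei. For cluster shares 0.5 nucleus was added before the log.

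No doublet caller was run. In its place, a nucleus with at least 3 UMIs from the marker list of another class was counted as mixed, and each main count was repeated without mixed nuclei. These were 22.4% to 65.8% of a mouse's inhibitory nuclei, 30.0% to 71.0% of its excitatory and 5.23% to 16.7% of its non-neuronal nuclei, shares that free RNA in the droplets also raises. Oligodendrocyte RNA marked 18.0% of inhibitory and 19.1% of excitatory nuclei, and astrocyte RNA 15.4% and 8.82%. Inhibitory neuron RNA marked 19.8% of excitatory nuclei, and excitatory neuron RNA 0.362% of inhibitory nuclei.

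The statistical steps were tested on simulated counts drawn from the real means, library sizes and dispersions. Each gene was drawn independently, without structure shared between genes of a mouse. The recovered and false calls may therefore differ in the real data. Of genes changed 1.5, 2 and 3 times, edgeR recovered 48 of 66, 63 of 67 and 65 of 65 in inhibitory nuclei over 18715 genes, and called 9 unchanged genes. It recovered 49 of 66, 63 of 67 and 66 of 66 in excitatory nuclei over 15982 genes, and 49 of 67, 60 of 66 and 66 of 66 in non-neuronal nuclei over 14325 genes, with 10 and 8 unchanged genes called. DESeq2 recovered 51, 65 and 65 of the same genes in inhibitory, 49, 62 and 66 in excitatory and 49, 60 and 66 in non-neuronal nuclei, and called 28, 17 and 16 unchanged genes. In astrocyte-like nuclei edgeR recovered 45 of 66, 64 of 67 and 66 of 66 over 11694 genes, and in inhibitory cluster 6 38 of 66, 61 of 65 and 66 of 66 over 7428 genes, with 11 and 7 unchanged genes called. There DESeq2 recovered 41, 62 and 66, and 28, 56 and 65, with 9 and 2 unchanged genes called. The limma test of the class difference recovered 38 of 60, 48 of 55 and 54 of 56 over 15931 genes, and called 5 unchanged genes. The permutation test was tried on 60 simulated values, called all 10 shifted ones and called 0 of the others. Gene positions came from GENCODE vM21 on GRCm38, the same assembly as mm10, which held 25821 of the symbols. Of 54 named genes placed, 16 overlap a gene on the opposite strand and 10 one on the same strand, so their counts can hold molecules of both.

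The endothelial-like fit fixed at the start asked for at least 4 mice with enough nuclei in each group. It could not be made, since the smallest groups had 3. Endothelial-like and mural-like nuclei were therefore pooled, a choice made after the data were seen, and so were the fits within clusters. The pooled fit also had 3 mice in its smallest groups and was run below that limit. Also chosen after the data were seen were the share of striatal projection neuron-like nuclei as a covariate and the counts without the 3 libraries that each held over 25% of a cluster (isoflurane female 5, isoflurane male 4 and oxygen male 1).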

Results

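The preoptic area takes part in sleep, body temperature and social and reproductive behaviour, and isoflurane is a volatile anaesthetic. Mice of both sexes breathed either 100% oxygen or a mixture of 98.8% oxygen with 1.2% isoflurane for 30 min between zeitgeber times 13 and 15, in chambers held in a bath at 37 °C. The series text gives the aim of this window as seeing rapid primary response genes with little secondary change. Nuclear RNA was counted in 5 oxygen females, 5 oxygen males, 5 isoflurane females and 5 isoflurane males. Of 150212 nuclei, 93621 were inhibitory, 26072 excitatory and 30519 non-neuronal in the authors' split. The median UMIs per nucleus of a mouse ran from 2678.5 to 6687 in inhibitory, 2848.5 to 6693 in excitatory and 1278 to 2289.5 in non-neuronal nuclei.

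The make-up of the samples and their depth were compared first, since both can move gene counts. Inhibitory nuclei made up 62.2% ± 6.37 of all nuclei in oxygen and 62.2% ± 6.01 in isoflurane (mean ± SD, n = 10 mice in each gas, permutation p = 0.994). Excitatory nuclei made up 18.5% ± 3.18 and 16.999% ± 3.69 (permutation p = 0.354), and non-neuronal nuclei 19.3% ± 7.51 and 20.8% ± 6.14 (permutation p = 0.629). Median UMIs per nucleus were 3976.55 ± 1109 and 3868.5 ± 551 in inhibitory nuclei (permutation p = 0.827), and the p was 0.950 in excitatory and 0.475 in non-neuronal nuclei. Of 96 clusters, 0 changed their share of their class by permutation test, with 3 at an unadjusted p below 0.05 and a smallest adjusted p of 0.878. With all mice, no difference in share or depth between the gases passed its test. In the share of nuclei per deposited class, excitatory nuclei passed without the 3 libraries that each held over 25% of a cluster (−3.60 percentage points, adjusted permutation p = 0.0340, against −1.51 with all mice).

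The first question was which genes isoflurane changed in inhibitory neurons, the largest class. Rapid response genes, which switch on within minutes of neuronal or growth factor signals, were called lower as a list by camera (adjusted p = 0.0201), a call lost with an estimated correlation (0.656), and no single gene passed. Of the core genes, the AP-1 member Fos had 11.7 ± 2.52 CPM in oxygen and 8.45 ± 1.49 in isoflurane (n = 10 in each gas), and the nuclear receptor gene Nr4a3 14.6 ± 5.20 and 8.98 ± 1.27. Ier2 stood the other way, with 1.47 ± 0.326 and 2.38 ± 0.677 CPM. The log2 fold changes of these 3 genes were −0.47, −0.71 and +0.68, with edgeR adjusted p of 0.269, 0.137 and 0.257. The other core genes ran from −0.33 for Npas4, −0.24 for Fosb, −0.15 for Nr4a1, −0.13 for Btg2, −0.01 for Junb and −0.00 for Egr4 to +0.08 for Dusp1, +0.10 for Egr1, +0.30 for Egr2 and +0.42 for Arc on the log2 scale.

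Across 18868 genes, edgeR called 0 in inhibitory nuclei, with 1390 at an unadjusted p below 0.05 (729 higher and 661 lower), while DESeq2 called 57 (19 higher and 38 lower). On simulated counts of this class DESeq2 called 28 unchanged genes and edgeR 9. Those counts also held genes made to change, so the number of false calls among the real ones can differ. Of the 37 rapid response genes, 12 had positive and 25 negative fold changes. Adjusted over the list alone, 2 genes passed upward (Ier2 and Zfp36) and 4 downward (Nr4a3, Fosl2, Fos and Npas4), against 0 over all genes. The core list itself did not pass (5 positive, 8 negative, camera adjusted p = 0.228). Leaving out 1 mouse ended the call of the rapid response list in 9 of 20 fits, with the highest adjusted p, 0.295, without isoflurane male 1.

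Other groups were lower in inhibitory nuclei by camera at the preset correlation, in small steps. With an estimated correlation 0 lists passed in any class. By fry 0 passed in 1 direction, and 5, 0 and 1 passed as mixed changes, up or down, in inhibitory, excitatory and non-neuronal nuclei. In inhibitory nuclei these were rapid response (fry mixed adjusted p = 0.00225), core (0.0220), delayed response (0.000221), MAPK feedback (0.0227) and cholesterol synthesis (0.0333). In non-neuronal nuclei it was rapid response (0.0136). Of 100 splits of these mice, 32 gave a camera p as small for the rapid response list in inhibitory nuclei. Calls at the preset correlation therefore do not by themselves show a change, here or in the other classes. Heat shock genes, which encode chaperones, fell as a list (14 of 16 negative, median log2 −0.13, adjusted p = 6.77e-06, or 0.398 with an estimated correlation), and 2 passed adjusted over the list alone, among them Dnajb1 (14.5 ± 1.37 to 11.5 ± 0.974 CPM) and Hsph1 (65.8 ± 9.12 to 55.9 ± 5.60 CPM). Cholesterol synthesis genes fell as a list (15 of 16 negative, median −0.09, adjusted p = 6.77e-06, or 0.398 with an estimated correlation), with 3 past the test adjusted over the list alone: Cyp51, Idi1 and Insig1. Delayed response genes fell as a list (11 of 17 negative, adjusted p = 0.00135, or 0.126 with an estimated correlation), with 4 past the test adjusted over the list alone, such as the prohormone convertase gene Pcsk1 (23.1 ± 3.10 to 16.7 ± 1.85 CPM). MAPK feedback genes (10 of 13 negative, 1 past the test over the list alone: Spry4) had an adjusted p of 0.00686, or 0.126 with an estimated correlation. Preoptic neuropeptides (15 of 24 negative, 1 past the test over the list alone: Crh) also had 0.00686, or 0.538 with an estimated correlation. The members named in these groups and in those of the other classes were chosen after their values were seen.

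Further lists called lower in inhibitory nuclei were glucocorticoid response (13 of 20 negative, adjusted p = 0.0016, or 0.398 with an estimated correlation) and sex-steroid signalling (12 of 14, p = 0.0022, or 0.638 with an estimated correlation). NRF2 and oxidative stress (12 of 16, adjusted p = 0.0143, or 0.623 with an estimated correlation) and unfolded protein response genes (15 of 18, adjusted p = 0.0307, or 0.731 with an estimated correlation) were lower too. Ribosomal protein genes (76 of 77 negative, median log2 −0.19) had an adjusted p of 3.24e-09, or 0.656 with an estimated correlation. Nuclear oxidative phosphorylation genes (69 of 78 negative, median −0.14) had 0.00135, or 0.731 with an estimated correlation. RNA of oligodendrocytes, which inhibitory neurons do not make, moved with these groups: all 11 markers were negative, with a median log2 of −0.17 (adjusted p = 1.95e-06, or 0.398 with an estimated correlation). Adjusted over the list alone, 0 genes of the glucocorticoid, sex-steroid, NRF2, unfolded protein, ribosomal and oxidative phosphorylation lists passed by edgeR. With 1 mouse left out, the unfolded protein response call was lost in 9 of 20 fits (highest adjusted p 0.660 without oxygen male 5). NRF2 was lost in 3 (highest 0.249 without oxygen male 5). Oxidative phosphorylation was lost without oxygen female 5, oxygen male 5, isoflurane female 5 or isoflurane male 1 (highest 0.595 without oxygen male 5). Preoptic neuropeptides lost their call without oxygen male 5 (0.0728) or isoflurane female 3 (0.0643) and sex-steroid signalling without isoflurane male 2 (0.0673). The call of the sex-steroid signalling list, inhibitory nuclei, was also lost with the striatal share as a covariate (adjusted p = 0.142). Without the 3 libraries that each held over 25% of a cluster, calls were lost for MAPK feedback and glucocorticoid response (both 0.147), unfolded protein response (0.138), NRF2 (0.0593) and oxidative phosphorylation (0.0524). Without mixed-marker nuclei the unfolded protein response call was lost (0.0647).

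In excitatory neurons, 1 gene changed. Narf, which encodes a nuclear prelamin A recognition factor (chromosome 11, 121237253 to 121255856 of GRCm38), fell from 32.8 ± 3.38 to 24.6 ± 2.17 CPM (n = 10 in each gas, log2 fold change −0.41, SE 0.07, edgeR adjusted p = 0.0289). Of 16114 genes, 1051 had an unadjusted p below 0.05 (505 higher and 546 lower), and DESeq2 called 3. No core gene passed: Fos had a log2 fold change of −0.20, Nr4a3 −0.44 (adjusted p = 0.761), Npas4 −0.10, Junb −0.06, Egr4 −0.02, Btg2 −0.02, Fosb −0.01, Nr4a1 +0.01, Egr1 +0.05, Arc +0.20, Dusp1 +0.32 and Ier2 +0.33. Egr2 was too low to be tested. The call of Narf was lost in 13 of the 20 fits that each left out 1 mouse, without mixed-marker nuclei, with equal nuclei per mouse and without the 3 libraries that each held over 25% of a cluster.

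The rapid response list (18 of 31 negative) and the core list (7 of 12 negative) did not pass in excitatory nuclei, with camera adjusted p of 0.566 and 0.766. Heat shock genes fell as a list (all 15 negative, median log2 −0.18, adjusted p = 3.64e-08, or 0.297 with an estimated correlation), and Hsph1 passed adjusted over the list alone (69.5 ± 9.61 to 55.7 ± 6.84 CPM). Delayed response genes (13 of 15 negative, adjusted p = 0.00104, or 0.297 with an estimated correlation) held 2 genes past the test over the list alone, the secretogranin gene Scg2 downward and Tll1 upward. Glucocorticoid response genes (16 of 20 negative) had an adjusted p of 0.00104, or 0.318 with an estimated correlation. Lower lists also included hypoxia and glycolysis (13 of 16 negative, adjusted p = 0.00897, or 0.362 with an estimated correlation) and unfolded protein response (11 of 16, adjusted p = 0.0119, or 0.592 with an estimated correlation, with Herpud1 past the test over the list alone). Sex-steroid signalling (9 of 13 negative, adjusted p = 0.0121, or 0.423 with an estimated correlation) and preoptic neuropeptides (15 of 23, adjusted p = 0.0332, or 0.513 with an estimated correlation) followed. The call of preoptic neuropeptides was lost in 10 of the 20 fits that left out 1 mouse, with the highest adjusted p, 0.317, without oxygen male 5, and without a filter (0.0550). Calls were also lost for unfolded protein response without oxygen male 5 (0.241) or oxygen female 5 (0.0769), sex-steroid signalling without isoflurane male 2 (0.153) or isoflurane female 2 (0.0592), and hypoxia and glycolysis without oxygen male 5 (0.0826). Without the 3 libraries that each held over 25% of a cluster, hypoxia and glycolysis and unfolded protein response lost their calls (both 0.0986). Without mixed-marker nuclei, hypoxia and glycolysis did (0.0595). Ribosomal protein genes (all 76 negative, median −0.20) had an adjusted p of 3.29e-14, or 0.639 with an estimated correlation, and oxidative phosphorylation genes (69 of 76, median −0.12) 0.000188, or 0.828 with an estimated correlation and 0.858 without oxygen male 5. All 11 markers of oligodendrocyte RNA were again negative beside them (median −0.24, adjusted p = 3.09e-08, or 0.318 with an estimated correlation).

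In non-neuronal nuclei single genes passed. Hes5, a target gene of Notch signalling, rose from 95.1 ± 16.7 to 163 ± 22.7 CPM (n = 10 in each gas, log2 fold change +0.78, SE 0.10, edgeR adjusted p = 0.000515). Thbs3, a thrombospondin of the extracellular matrix, rose from 22.6 ± 5.20 to 41.0 ± 5.85 CPM (+0.82, SE 0.12, adjusted p = 0.00261). Ccn1, a matrix protein gene that growth factors and mechanical force induce, rose from 8.02 ± 2.08 to 20.7 ± 9.68 CPM (+1.45, SE 0.26, adjusted p = 0.0307). Usp53, of the ubiquitin protease family, fell from 258 ± 66.3 to 171 ± 20.5 CPM (−0.58, SE 0.11, adjusted p = 0.0470).

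In all, edgeR called 9 of 14467 genes in non-neuronal nuclei, 8 higher and 1 lower, with 1107 at an unadjusted p below 0.05, while DESeq2 called 33. On simulated counts of this class, which also held genes made to change, DESeq2 called 16 unchanged genes and edgeR 8. The number of false calls among the real ones can therefore differ. The other genes that rose were Gm10138 (+0.96, adjusted p = 0.00454), a transcript antisense to Ivns1abp, Wipf3 (+0.68, adjusted p = 0.00589), Lrrc51 (+0.53, adjusted p = 0.0440), Arhgef10l (+0.45, adjusted p = 0.0474) and Prr14 (+0.34, adjusted p = 0.0163). On GRCm38, Hes5 lies on chromosome 4 from 154960923 to 154962371, Thbs3 on chromosome 3 from 89215180 to 89226837, Ccn1 on chromosome 3 from 145646976 to 145649981 and Usp53 on chromosome 3 from 122931493 to 122984510. Hes5 overlaps Gm20421, Thbs3 overlaps Mtx1, Gm10138 overlaps Ivns1abp, Wipf3 overlaps Scrn1 and Lrrc51 overlaps Lamtor1 on the opposite strand, and without stated strand use their molecules cannot be told apart. Leaving out 1 mouse ended the call of Arhgef10l in 17, Lrrc51 in 15, Usp53 in 13, Ccn1 in 11 and Prr14 in 4 of the 20 fits. Without mixed-marker nuclei edgeR called 3 genes, and of the 9 genes all but Hes5, Thbs3 and Wipf3 lost their calls. With equal nuclei per mouse the calls of Thbs3, Gm10138, Prr14, Arhgef10l and Lrrc51 were lost, and without a filter those of Ccn1, Lrrc51 and Prr14. Without the 3 libraries that each held over 25% of a cluster, Arhgef10l, Ccn1, Lrrc51, Prr14 and Usp53 lost theirs. With median UMIs as a covariate Arhgef10l, Lrrc51 and Usp53 did, and with RLE factors Arhgef10l.

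The rapid response list rose in non-neuronal nuclei: 25 of 29 genes were positive, with a median log2 of +0.29 (camera adjusted p = 1.85e-11, or 0.105 with an estimated correlation). The core list rose likewise (9 of 10 positive, median +0.70, adjusted p = 2.27e-10, or 0.105 with an estimated correlation). Adjusted over the list alone, 11 rapid response genes rose, against 0 over all genes: Dusp1, Ier2, Egr1, Zfp36, Btg2, Junb, Nr4a1, Egr3, Jun, Fosl2 and Sik1. Ier2 had 4.15 CPM in oxygen and 15.1 in isoflurane (log2 fold change +1.93, adjusted p over all genes = 0.0666), Dusp1 10.99 and 24.0 (+1.19, 0.0654) and Egr1 21.0 and 34.6 (+0.73, 0.0704). Btg2 had +1.16, Nr4a1 +0.86, Junb +0.66, Egr4 +0.31, Fos +0.29, Arc +0.02 and Nr4a3 −0.07, and Fosb, Egr2 and Npas4 were too low to be tested. The list of vascular RNA did not pass beside them (camera adjusted p = 0.543).

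Circadian clock genes rose as a list in non-neuronal nuclei (14 of 20 positive, median +0.12, camera adjusted p = 0.00148, or 0.495 with an estimated correlation), and 0 of them passed adjusted over the list alone by edgeR. Glucocorticoid response genes fell (14 of 21 negative, median −0.20, adjusted p = 0.0143, or 0.929 with an estimated correlation), with Zbtb16 (141 ± 43.2 to 84.9 ± 41.3 CPM) and Tsc22d3 (119 ± 14.0 to 100.2 ± 13.4 CPM) past the test adjusted over the list alone. Ribosomal protein genes (all 76 negative, median −0.20, adjusted p = 8.34e-11, or 0.929 with an estimated correlation) and oxidative phosphorylation genes (69 of 76, median −0.13, adjusted p = 4.10e-05, or 0.929 with an estimated correlation and 0.311 without oxygen male 5) were lower in this class too. The nuclei of the 3 classes come from the same 20 libraries, so a like direction in them is not independent evidence. The call of the glucocorticoid list was lost without oxygen male 1, isoflurane female 4, isoflurane female 5 or isoflurane male 4, and without the 3 libraries that each held over 25% of a cluster (adjusted p = 0.692).

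Lists of the molecular targets of anaesthetics and of sleep control did not pass in any class. GABA-A and glycine receptor subunits had camera adjusted p of 0.374, 0.766 and 0.197 in inhibitory, excitatory and non-neuronal nuclei, and two-pore potassium, HCN and GIRK channels 0.561, 0.621 and 0.898. Adjusted over the list alone, 1 receptor subunit gene passed downward in non-neuronal nuclei and 1 channel gene downward in excitatory nuclei. For ionotropic glutamate receptors the values were 0.3998, 0.464 and 0.606, for presynaptic release machinery 0.969, 0.501 and 0.866, and for sleep-state and arousal receptors 0.228, 0.601 and 0.325. Cold-inducible genes (0.627, 0.566 and 0.940), sex chromosome genes (0.368, 0.766 and 0.762), X escape genes (0.530, 0.709 and 0.643) and mitochondrially encoded genes (0.814, 0.566 and 0.866) did not pass either. The same held for RNA of astrocytes (0.228, 0.402 and 0.380), microglia (0.580, 0.499 and 0.468), vascular cells (0.627 and 0.499 in the neuronal classes), ependymal and choroid plexus cells (0.285, 0.597 and 0.762) and neurons (0.627, 0.686 and 0.643). Excitatory neuron RNA had 0.419 and 0.843 in inhibitory and excitatory nuclei, inhibitory neuron RNA 0.228, 0.566 and 0.643, and activated microglia and cytokine genes 0.179 and 0.606 in inhibitory and non-neuronal nuclei. Of the lists called in one class, some did not pass in another: in inhibitory nuclei circadian clock (0.263) and hypoxia and glycolysis (0.0536), and in excitatory nuclei MAPK feedback (0.467), circadian clock (0.766), NRF2 (0.0536) and cholesterol synthesis (0.566). In non-neuronal nuclei these were delayed response (0.866), MAPK feedback (0.643), heat shock (0.468), unfolded protein response (0.146), NRF2 (0.468), hypoxia and glycolysis (0.643), cholesterol synthesis (0.799), preoptic neuropeptides (0.308), sex-steroid signalling (0.866) and oligodendrocyte RNA (0.0634). Median, mean and test differed in sign for these lists, none of them called: core, circadian and presynaptic in excitatory nuclei, and heat shock, two-pore potassium, glutamate, cholesterol, sex-steroid, X escape, mitochondrially encoded and ependymal in non-neuronal nuclei.

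The non-neuronal class was then separated into types named by fixed markers. In astrocyte-like nuclei (13387 nuclei, 20 mice), single genes changed while the core rapid response level did not pass its test. Usp53 fell from 486 ± 61.9 to 284 ± 39.1 CPM (n = 10 in each gas, log2 fold change −0.77, edgeR adjusted p = 6.78e-07). Txnip, an inhibitor of thioredoxin that glucose induces, fell from 22.7 ± 5.80 to 12.8 ± 4.31 CPM (−0.88, adjusted p = 0.00978). Megf9 (−0.64, adjusted p = 0.0088), the kinase gene Map3k19 (−0.62, 89.0 ± 14.2 to 58.0 ± 10.4 CPM) and the adhesion scaffold gene Nedd9 (−0.54, 63.2 ± 5.68 to 43.6 ± 4.45 CPM) fell as well. The largest rises were in Gm10138 (+1.06, adjusted p = 0.00465), Gm27239 (+0.90, adjusted p = 0.0345), AI849053 (+0.88), Wipf3 (+0.83) and Thbs3 (+0.76, 39.7 ± 13.5 to 70.3 ± 12.9 CPM). Of 11874 genes, 31 passed, 18 higher and 13 lower. Chosen after their values were seen, Hes5 (165 ± 19.8 to 278 ± 36.5 CPM, adjusted p = 6.78e-07) and the receptor gene Notch1 (65.0 ± 9.39 to 89.3 ± 17.2 CPM, adjusted p = 0.0345) rose. Chosen in the same way, the transcription factor gene Foxo1 (230.3 ± 41.2 to 164 ± 19.3 CPM, adjusted p = 0.00368) and the polyamine enzyme gene Sat1 (493 ± 58.5 to 356 ± 46.4 CPM, adjusted p = 0.00316) fell. Without oxygen male 2 the count was 20, and the call of Gm27239 was lost in 11 of the 20 fits that left out 1 mouse, without mixed-marker nuclei and without the 3 libraries that each held over 25% of a cluster.

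**Figure D1:**
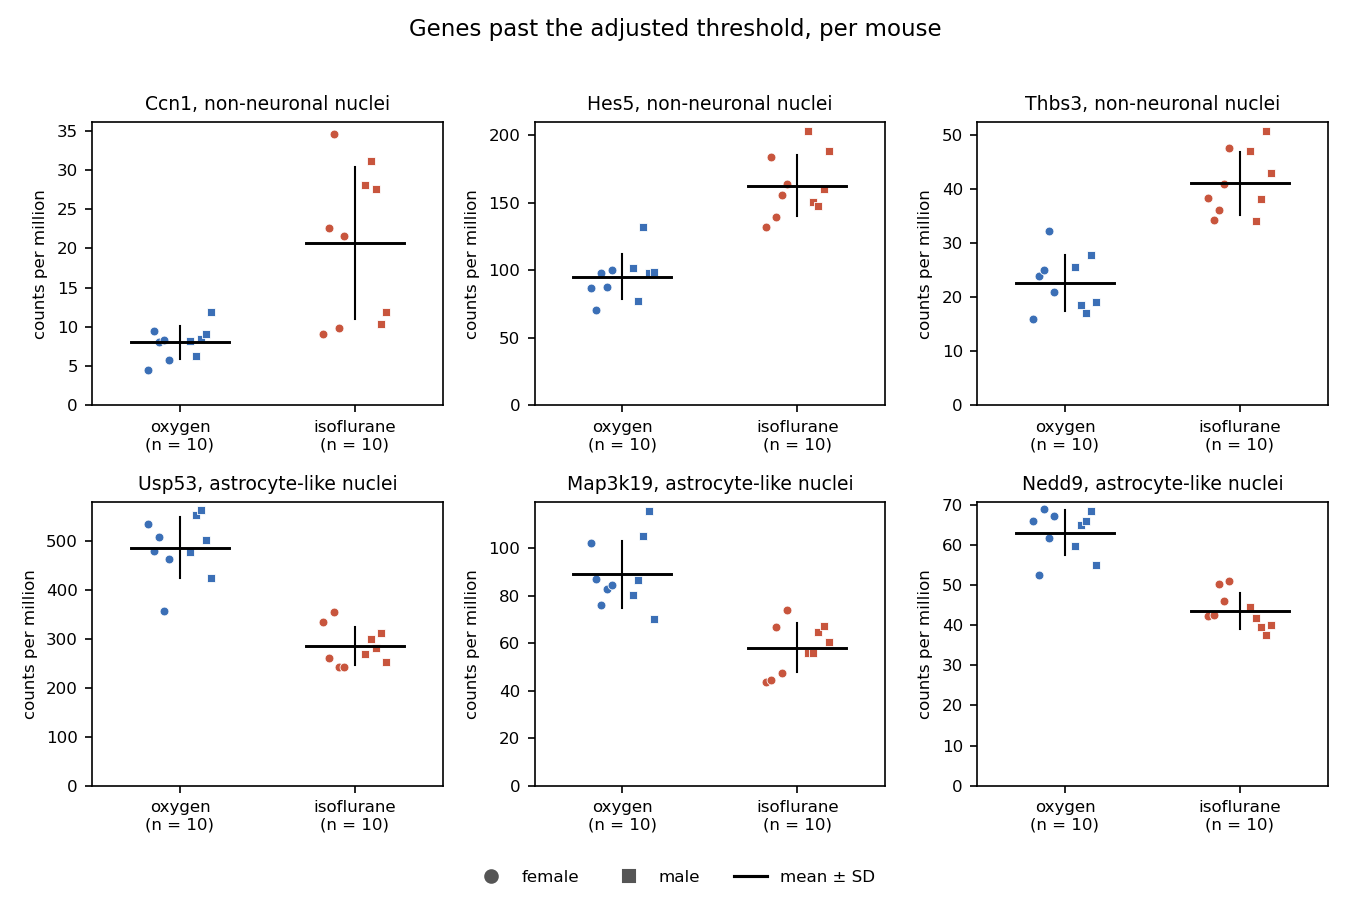
Levels in CPM (vertical axes) of Ccn1, Hes5 and Thbs3 in non-neuronal nuclei and of Usp53, Map3k19 and Nedd9 in astrocyte-like nuclei, in oxygen and isoflurane. Each point is a mouse (circles female, squares male, n = 10 in each gas), the bar is the mean and the error bar the SD; Nedd9 lies at 63.2 ± 5.68 CPM in oxygen and 43.6 ± 4.45 in isoflurane, while the points of Ccn1 overlap between the gases.

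In mature oligodendrocyte-like nuclei (6731 nuclei), 3 of 8170 genes rose and 0 fell: the histone gene Hist1h2bc (34.6 ± 11.5 to 68.1 ± 17.7 CPM, log2 fold change +0.90, edgeR adjusted p = 0.00708), 2810410L24Rik (+0.74, adjusted p = 0.0312) and 2900052L18Rik (+0.56, adjusted p = 0.0366). The calls of 2810410L24Rik and 2900052L18Rik were lost in 8 and 11 of the 20 fits that left out 1 mouse and by DESeq2. That of 2810410L24Rik was also lost without the 3 libraries that each held over 25% of a cluster. In oligodendrocyte precursor-like nuclei (2308 nuclei), edgeR called 0 of 5324 genes with 246 at an unadjusted p below 0.05, and in microglia-like nuclei (700 nuclei of 17 mice) 0 of 1619 with 105. DESeq2 also called 0 genes in both types.

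Rapid response genes rose in cells of blood vessels. The core level of endothelial-like nuclei (429 nuclei) was 311 ± 244 CPM in 6 oxygen mice and 3406 ± 989 in 7 isoflurane mice, a log2 difference of +4.66 (exact permutation p = 0.00143, the smallest that these mice allow, adjusted over 7 types to 0.01). In mural-like nuclei, of cells around vessels (406 nuclei), it was 325 ± 137 CPM in 6 and 3176 ± 1670 in 6 mice, a log2 difference of +3.25 (exact permutation p = 0.005, adjusted p = 0.0175). These log2 differences average the log of each mouse within each sex, so mice with low levels weigh more in them than in the mean CPM, and they can differ from the ratio of the means. In endothelial-like nuclei the effect was +5.57 in females and +3.75 in males, a difference that did not pass (exact permutation p = 0.939). By the same exact permutation test the level did not pass in microglia-like (127.6 ± 62.0 to 187.6 ± 74.5 CPM, +1.23, adjusted p = 0.109), fibroblast-like (+0.54, 0.109), oligodendrocyte precursor-like (+0.26, 0.292), mature oligodendrocyte-like (+0.19, 0.398) and astrocyte-like nuclei (+0.08, unadjusted p = 0.601). Whether the effect differs between types was not tested.

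The endothelial-like and mural-like nuclei were pooled after the data were seen. Non-neuronal cluster 16 (leading genes Myh11, Acta2 and Cnn1, 83 nuclei) had no type name and was not included. The smallest groups of the pooled fit held 3 mice, below the 4 per group that other gene fits required. Pooling gave 835 nuclei in 6 oxygen and 9 isoflurane mice. Rapid response and other genes rose many-fold in them: Nr4a1 from 22.1 ± 18.5 to 515 ± 199 CPM (log2 fold change +4.33, edgeR adjusted p = 1.63e-09), Ccn1 from 10.3 ± 8.24 to 468 ± 277 CPM (+5.08, adjusted p = 1.29e-08) and Atf3 from 3.37 to 115 CPM (+4.90). Junb rose from 43.8 to 597 CPM (+4.21) and Apold1, an endothelial immediate early gene, from 32.9 to 489 CPM (+3.79). In 1 isoflurane mouse, female 1 with 11 such nuclei, Ccn1 had 0 UMIs. Of the core genes, Egr1 (+3.65), Dusp1 (+3.57), Fos (+3.54), Ier2 (+2.80) and Btg2 (+2.56) rose as well. In all, 32 of 2926 genes passed, 31 higher and 1 lower, the kinase gene Cdk19 (423 to 221 CPM, −0.91, adjusted p = 0.0488). The call of Cdk19 was lost in 11 of the 15 fits that left out 1 mouse, by DESeq2, with RLE factors, without a filter, without mixed-marker nuclei and without the 3 libraries that each held over 25% of a cluster. Chosen after their values were seen, Jun (+2.68), the metalloprotease gene Adamts1 (+2.62) and Klf4 (+1.77) were among those that rose. The core level was 313 ± 154 CPM in oxygen, with a highest mouse of 554, and 2863 ± 1348 in isoflurane, with a lowest of 1348 (log2 difference +3.26, exact permutation p = 0.00051, the smallest possible). The effect was +2.90 in females and +3.62 in males, a difference that did not pass (exact permutation p = 0.385).

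After thinning to equal depth, 26.8% ± 10.4 of the pooled vascular nuclei held a core UMI in 6 oxygen mice and 76.3% ± 10.4 in 9 isoflurane mice (exact permutation p = 0.00051), with median UMIs of 1500 and 1527. As a background, 11.2% of astrocyte-like nuclei held one over both gases, at a median of 1686 UMIs. The pooled vascular nuclei were 2.18% ± 2.10 of non-neuronal nuclei in oxygen and 2.75% ± 2.01 in isoflurane (n = 10 in each gas, permutation p = 0.537). Endothelial-like nuclei alone were 0.99% and 1.56%, and mural-like nuclei 1.187% and 1.195%. Neither share passed its test, but the pooled fit did not adjust for this mix, which can move genes of a single type. The core level of all non-neuronal nuclei was 129 ± 37.5 and 219 ± 74.7 CPM (log2 difference +0.72, permutation p = 0.00728), and without the pooled vascular nuclei 125 ± 33.4 and 140 ± 32.9 CPM (+0.18, permutation p = 0.288). At equal depth 11.7% ± 2.89 and 14.2% ± 2.62 of non-neuronal nuclei held a core UMI, a difference that did not pass (permutation p = 0.0638, adjusted over the classes 0.192), nor did it without thinning (permutation p = 0.217). The shares at equal depth were 10.3% and 9.92% in inhibitory (permutation p = 0.556) and 9.57% and 9.37% in excitatory nuclei (permutation p = 0.713).

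**Figure D2:**
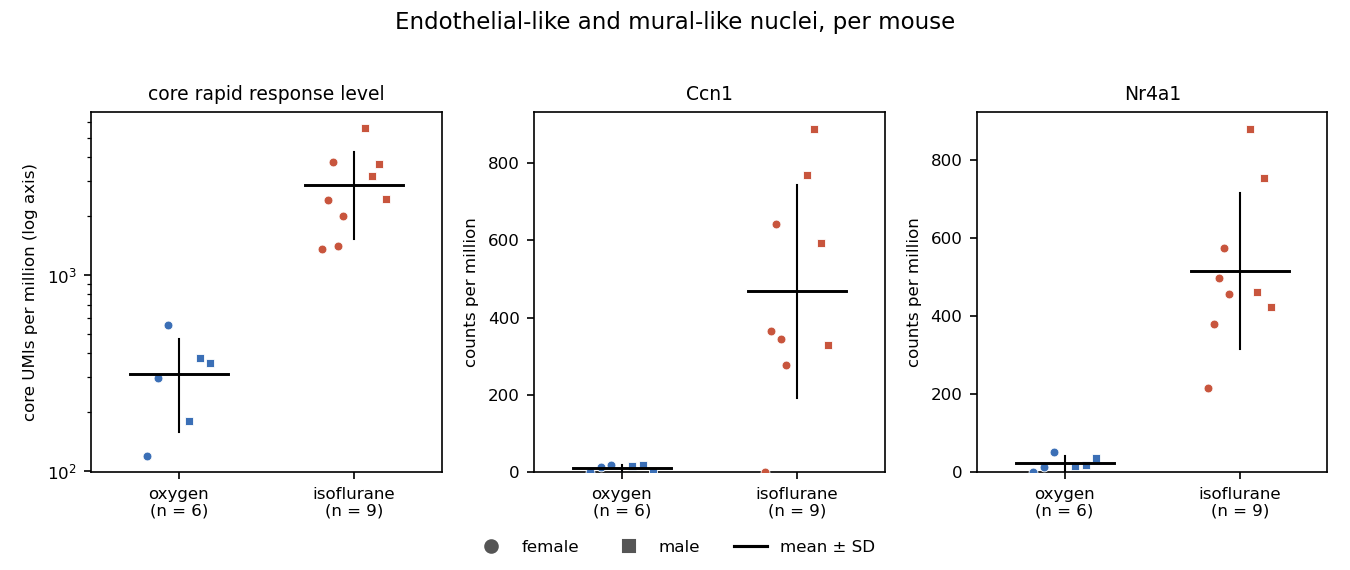
Core rapid response level (CPM, log axis) and levels of Ccn1 and Nr4a1 (CPM) in endothelial-like and mural-like nuclei. Each point is a mouse (circles female, squares male; 6 in oxygen, 9 in isoflurane), the bar is the mean and the error bar the SD; every isoflurane mouse has a core level above the highest oxygen mouse, at 554, and 1 isoflurane mouse has Ccn1 at 0.

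Neurons were next compared cluster by cluster, since a class sum can hide cell types that move apart. The core rapid response level changed in 8 of 35 inhibitory clusters (2 higher, 6 lower), 3 of 21 excitatory clusters (1 higher, 2 lower) and 0 of 6 non-neuronal clusters by exact permutation test, with 14, 5 and 0 at an unadjusted p below 0.05. The endothelial-like and mural-like clusters, with 13 and 12 mice, had too few mice for this test. Of the 6 clusters with the smallest p, 2 were higher. Excitatory cluster 16 (leading genes E130114P18Rik, Tns3 and Etv1, 615 nuclei) went from 56.3 ± 12.5 to 206 ± 76.5 CPM (n = 10 in each gas, log2 difference +1.79, permutation p = 3.15e-05, the smallest possible, adjusted p = 0.000651). Inhibitory cluster 6 (Folh1, Prkcq and Ntng2, 4208 nuclei), which carried markers of striatal projection neurons, went from 109.9 ± 37.4 to 456 ± 471 CPM (+1.79, with the same p). The isoflurane mean and SD were raised by isoflurane male 4, at 1779 CPM on 13 nuclei. At equal depth the shares of nuclei with a core UMI went from 5.49% to 14.5% in excitatory cluster 16 and from 10.2% to 20.7% in inhibitory cluster 6. Over both gases the share was 11.1% in all striatal projection neuron-like nuclei, and ran from 7.04% to 23.3% over the 11 named neuron types.

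The other 4 of these clusters had lower core levels under isoflurane. Inhibitory cluster 17 (Tafa4, Lgr5 and Lama3, 2118 nuclei) went from 107 ± 15.3 to 58.8 ± 18.7 CPM (n = 10 in each gas, log2 difference −0.91, permutation p = 3.15e-05, adjusted p = 0.000651). Inhibitory cluster 26 (1043 nuclei), led by Th, which encodes tyrosine hydroxylase of dopamine synthesis, and by Gem and Atp8b1, went from 739 ± 232 to 379.9 ± 93.2 CPM (−0.94, permutation p = 6.30e-05, adjusted p = 0.000976). Inhibitory cluster 13 (Otx2os1, Gm29478 and Prdm16, 2924 nuclei), septal neuron-like, went from 172 ± 48.9 to 100.3 ± 23.6 CPM (−0.76, permutation p = 0.000126, adjusted p = 0.00156). Excitatory cluster 18 (Foxp2, Cntn4 and Vcan, 590 nuclei) went from 169.7 ± 100.7 to 54.5 ± 18.1 CPM (−1.46, permutation p = 0.000693, adjusted p = 0.00716), and this call was lost without mixed-marker nuclei (−1.35, adjusted p = 0.146). In the 6 clusters, all 10 isoflurane mice stood on the same side of the oxygen median of their sex. The other clusters past the test were inhibitory 3 (−0.53), 36 (−1.06), 7 (+0.49) and 21 (−0.48), each at an adjusted p of 0.0383, and excitatory 23 (−0.86, adjusted p = 0.0398). Without mixed-marker nuclei the calls of inhibitory clusters 3 (−0.41, adjusted p = 0.184), 7 (+0.36, 0.225) and 21 (−0.25, 0.538) were lost, and inhibitory cluster 36 and excitatory cluster 23 had too few mice with enough nuclei to be tested. Warm-sensitive preoptic excitatory neuron-like cluster 11 (+0.50, adjusted p = 0.178) and the cholinergic neuron-like cluster (−0.02, adjusted p = 0.974) did not pass the permutation test, and the effect differed between the sexes in 0 clusters.

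**Figure D3:**
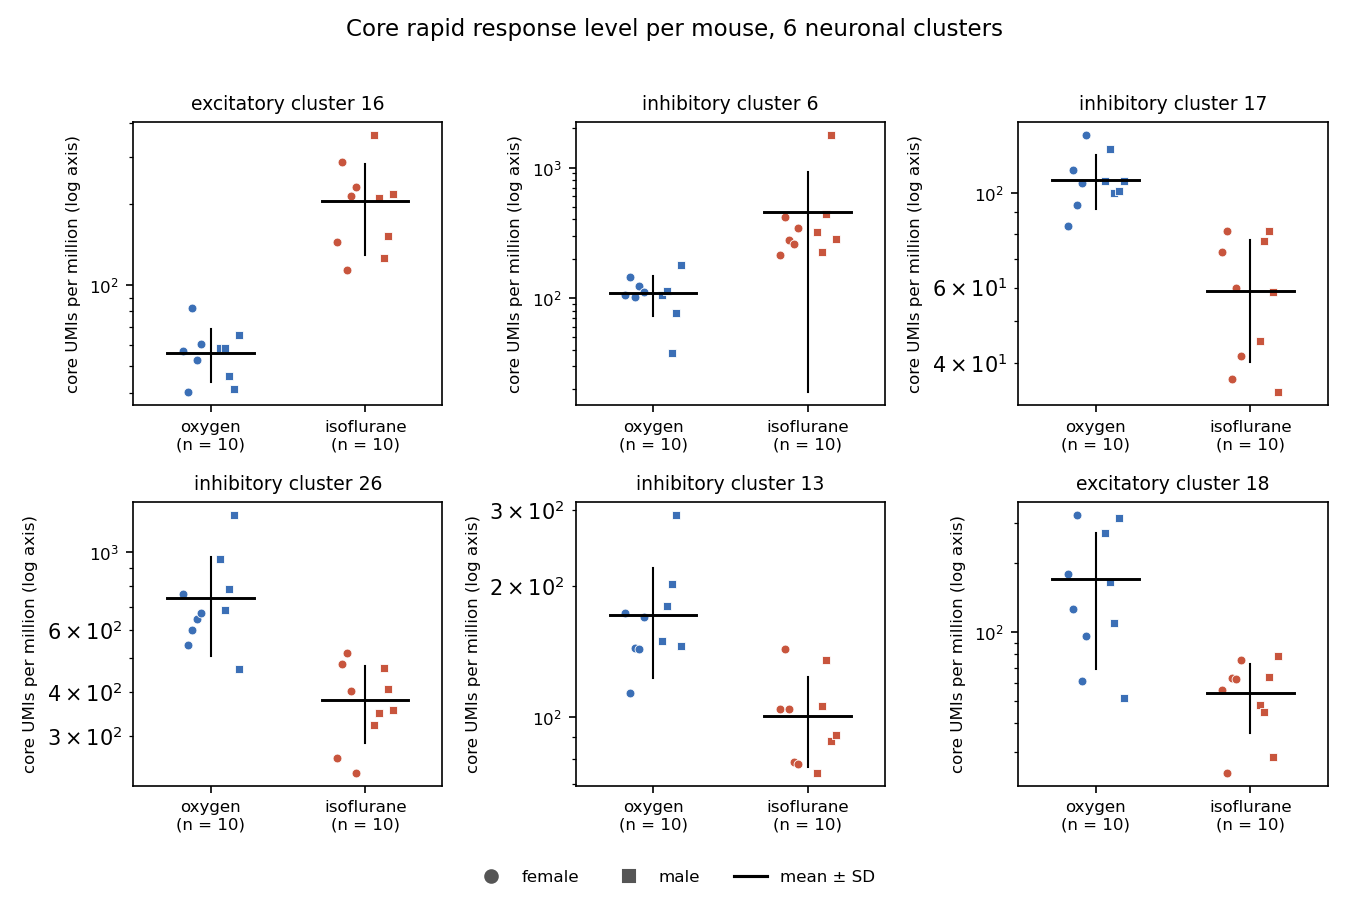
Core rapid response level per mouse (CPM, log axis) in 6 neuronal clusters in oxygen and isoflurane. Each point is a mouse (circles female, squares male, n = 10 in each gas), the bar is the mean and the error bar the SD; excitatory cluster 16 and inhibitory cluster 6 lie higher in isoflurane, and inhibitory clusters 17, 26 and 13 and excitatory cluster 18 lower.

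Genes were tested within these 6 clusters, which were picked by their core level, so that core genes among the calls are not independent of that choice. In inhibitory cluster 6, 7 of 7695 genes rose, with 403 at an unadjusted p below 0.05: Egr3 (22.1 to 75.6 CPM, log2 fold change +1.68, edgeR adjusted p = 4.12e-05), Egr1 (26.3 to 102 CPM, +1.45), the clock gene Per1 (18.1 to 56.9 CPM, +1.38), Nr4a1 (+1.29), Junb (+1.20) and 2 more. These 2, outside the naming rule, were the synaptic scaffold gene Homer1 (+1.11) and Thbs3 (+0.78). In inhibitory cluster 26, 9 of 5392 genes fell: Npas4 (61.5 ± 38.6 to 14.3 ± 10.4 CPM, −2.04, adjusted p = 0.00742), Nr4a3 (215 to 78.6 CPM, −1.51), Pcsk1 (55.0 to 25.6 CPM, −1.51), Fos (121 to 49.7 CPM, −1.22) and Fosl2 (97.3 to 48.1 CPM, −1.05), and, chosen after their values were seen, 1700016P03Rik, Olfm3, Zdbf2 and Scg2. In inhibitory cluster 13, 3 of 9386 genes fell: Fos (21.6 to 6.98 CPM, −1.58, adjusted p = 0.012), 1700016P03Rik (76.7 to 29.7 CPM, −1.39, adjusted p = 1.86e-07), the host transcript of the activity-linked Mir132 and Mir212, and Mir670hg (182 to 119.9 CPM, −0.57, adjusted p = 0.0103). In excitatory cluster 16, 1 of 3008 genes rose, Gem, an activity-induced small GTPase gene (29.2 ± 23.8 to 168 ± 96.1 CPM, +2.37, adjusted p = 0.000268), a call lost without mixed-marker nuclei. In inhibitory cluster 17 and excitatory cluster 18 edgeR called 0 of 8929 and 0 of 3274 genes, with 447 and 188 at an unadjusted p below 0.05, and DESeq2 called 0 in each. Without the 3 libraries that each held over 25% of a cluster, 2 genes passed in inhibitory cluster 26 and the calls of Npas4, Nr4a3, Pcsk1 and Fosl2 were lost, as was that of Mir670hg in inhibitory cluster 13. Leaving out 1 mouse ended the call of Fos in inhibitory cluster 13 without oxygen male 4 (adjusted p = 0.163) or isoflurane female 1 (0.0562). It ended that of Pcsk1 in inhibitory cluster 26 in 4 of 20 fits (highest 0.126 without oxygen female 2). The call of Nr4a1 in inhibitory cluster 6 was lost by DESeq2.

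Whether isoflurane acted alike in both sexes was tested as an interaction. By edgeR, 0 genes passed in inhibitory, excitatory and non-neuronal nuclei, with 156, 267 and 251 at an unadjusted p below 0.05, DESeq2 called 0 in each class, and the smallest edgeR adjusted p among 103 named genes was 0.989. Within females alone edgeR called 0, 0 and 2 genes in the 3 classes, with 619, 616 and 729 at an unadjusted p below 0.05, and within males alone 0, 0 and 0, with 738, 585 and 621. The effect on inhibitory and excitatory neurons was compared within each mouse by limma: 0 of 16080 genes differed, with 796 at an unadjusted p below 0.05. The differences, inhibitory minus excitatory, were −0.26 for Fos (adjusted p = 0.961), −0.28 for Nr4a3 (0.961), −0.27 for Dusp1 (0.929) and +0.31 for Ier2 (0.961) on the log2 scale.

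Females and males that breathed oxygen differed mainly in genes of the sex chromosomes. The sex labels of all 20 libraries were checked with them: in inhibitory nuclei Xist ran from 851 to 1332 CPM in the 10 females and from 0.136 to 1.27 in the 10 males of both gases. In inhibitory nuclei 11 genes passed (6 higher and 5 lower in females), in excitatory 12 (7 and 5) and in non-neuronal nuclei 7 (3 and 4) by edgeR, with 405, 460 and 281 at an unadjusted p below 0.05. Xist, which silences an X chromosome, had 1079.5 ± 176 CPM in inhibitory nuclei of females and 0.655 ± 0.259 in males (SD, n = 5 each), and its antisense partner Tsix 399.7 ± 72.6 and 1.13 ± 0.287, counts that cannot be told apart where the genes overlap without strand. The X-linked genes Ddx3x (37.6 ± 1.57 and 23.6 ± 1.17 CPM, log2 difference +0.67), Eif2s3x (22.4 ± 1.31 and 14.8 ± 0.977, +0.60) and the histone demethylase gene Kdm6a (86.0 ± 6.45 and 62.2 ± 4.16, +0.47), which escape silencing, were higher in females. The Y-linked genes Uty (0.181 and 129 ± 12.7 CPM), Eif2s3y (0.0945 and 102 ± 14.8), Kdm5d (0.0906 and 65.0 ± 4.67) and Ddx3y (0.0558 and 39.7 ± 2.58) were near 0 in females. In excitatory nuclei the autosomal gene Myo3b, a myosin, was higher in females (15.1 ± 1.01 and 9.57 ± 1.54 CPM, +0.63, adjusted p = 0.0492). This call was lost in 17 of the 20 fits that left out 1 mouse, with RLE factors, without a filter, without mixed-marker nuclei, with median UMIs as a covariate, with equal nuclei per mouse and without the 3 libraries that each held over 25% of a cluster.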

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

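Of the tests in this part, those of the difference between clusters, of depth and free RNA in the neuronal clusters, and of free RNA from neurons and of share, level and depth of vascular nuclei were chosen only after the result was seen. The fits within clusters and in pooled vascular nuclei, and the fit with the striatal share as a covariate were added then too.

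The isoflurane effect on the core rapid response level differed between neuronal clusters. The test took in all 45 neuronal clusters with enough nuclei in each of the 20 mice, none picked by its effect, and centred each mouse over the clusters so that a common effect drops out. The sum of squared effects, each over its permutation SD, was 154 against a mean of 45 over the permutations (exact permutation p = 3.15e-05, the smallest possible). Without mixed-marker nuclei it was 90.1 against 32 in 32 clusters (exact permutation p = 3.15e-05, n = 20 mice). Centred effects ran from −1.32 to +1.93 on the log2 scale in all nuclei.

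In the 6 clusters with the smallest p, depth of the nuclei did not produce the pattern, since the shares at equal depth passed in all 6, with a highest permutation p of 0.00321. For free RNA spread evenly through a library, 3 clusters passed upward and 8 downward. A change in its content alone would move clusters the same way. A change in its amount could draw high clusters down and low clusters up, so this test cannot exclude free RNA. Without mixed-marker nuclei 5 of the 6 clusters stayed past the threshold, while the test fixed beforehand asked for all 6. Excitatory cluster 18 went from −1.46 to −1.35 with an adjusted permutation p of 0.146 on fewer nuclei, so a part from mixed nuclei cannot be told apart. Dissection and free RNA, also that of single types, stay open as well.

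The second pattern was the higher rapid response list in non-neuronal nuclei, a camera call lost with an estimated correlation (adjusted p = 0.105) and by fry in 1 direction (0.0756). At the preset correlation it did not rest on one mouse, as the highest adjusted p with each mouse left out was 2.33e-09, and deeper vascular nuclei do not account for it, since their thinned share differed by 50.03 percentage points. Leaving out endothelial-like and mural-like nuclei lowered the log2 difference from 0.721 to 0.177, which was what more vascular nuclei would give, but this removal cannot part their number from their level. Their share alone would add 1.38 of the 75.2 CPM of core UMIs that they brought, which excludes it as the whole cause, and a higher level within them (+3.26) fits. Free RNA from neurons cannot be told apart for the rest: the 12 members negative in both neuronal classes had a median of 0.218 in non-neuronal nuclei with members on both sides, and a response of vessels to isoflurane stays open beside it.

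Mice were regrouped at random into groups of the same sizes, 100 splits per result with the real one included. For genes changed by isoflurane, 1 of 100 splits gave as many in non-neuronal nuclei (9 real genes against a highest other of 7). In astrocyte-like nuclei it was 1 split (31 against 5), and in mature oligodendrocyte-like nuclei 1 (3 against 2). In pooled vascular nuclei 2 splits gave as many (32 against 32). Chance could be excluded with a wide margin only in astrocyte-like nuclei. Elsewhere the margin was small or absent, and calls of single genes were lost with 1 mouse left out. The splits also did not repeat the pooling of vascular nuclei, which was chosen after the data were seen. In excitatory nuclei 4 splits gave as many as the 1 real gene, Narf (highest other 259). Its call was lost in most of the fits that left out 1 mouse, so chance was not excluded there. The numbers of splits were not adjusted for the number of results. Inhibitory cluster 26 (1 split, 9 against 4), inhibitory cluster 13 (3 splits, 3 against 10) and inhibitory cluster 6 (2 splits, 7 against 55) had been picked by their core level with the real groups, and the splits did not pick anew, so these counts exclude nothing. Chance could not be excluded in excitatory cluster 16 (11 splits, 1 against 3). With 0 real genes, all 100 splits gave as many in inhibitory nuclei (highest 881), inhibitory cluster 17 (7), excitatory cluster 18 (2), oligodendrocyte precursor-like nuclei (12), microglia-like nuclei (51) and the class difference (4). The same held for the interaction in inhibitory (2033), excitatory (146) and non-neuronal nuclei (0). For clusters with a changed core level, 1 split gave as many as the 8 inhibitory (highest other 3) and 1 as many as the 3 excitatory ones (highest other 1), and all 100 gave the 0 non-neuronal ones among those tested (highest other 0). For sex differences, 1 split gave as many in inhibitory (11 against 0) and in excitatory nuclei (12 against 0), and 4 in non-neuronal nuclei (7 against 275). The unadjusted camera p of the rapid response list was matched by 1 split in non-neuronal nuclei (5.78e-13 against 4.21e-12), by 32 in inhibitory (0.0073 against 9.21e-15) and by 67 in excitatory nuclei (0.337 against 7.62e-08). By this p, at the preset correlation, no other split came as low for this list in non-neuronal nuclei, by a small margin. In the neuronal classes chance could not be excluded. The list did not pass in non-neuronal nuclei with an estimated correlation (adjusted p = 0.105) or by fry in 1 direction (0.0756), while it passed by fry as a mixed change (0.0136). These tests were not computed for the splits. Splits that call 259 genes in excitatory nuclei, 275 between the sexes in non-neuronal nuclei, 55 in inhibitory cluster 6 or 51 in microglia-like nuclei, several times the real counts, point to a structure of the mice there that was not traced.

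Splits that call 881 or 2033 genes where the real one calls 0 point to a structure among the mice. In inhibitory nuclei the first principal component (31.2% of the variance) followed the share of striatal projection neuron-like nuclei, which ran from 5.57% to 46.8% of a mouse's inhibitory nuclei (Pearson r = 0.871 and Spearman rho = 0.865, permutation p = 1e-05 each, the smallest possible). Without the 2 mice farthest from the median share, isoflurane male 2 and oxygen male 3, r was 0.8286 (permutation p = 6e-05). This fits a difference in dissection between mice, and no biological explanation was tested. The share did not differ between gases (21.5% ± 10.1 in oxygen, 25.9% ± 12.3 in isoflurane, n = 10 each, permutation p = 0.398), and with it as a covariate edgeR called 7 genes in inhibitory nuclei.

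Single mice stood far from the other 4 of their group in 29 of 420 groups of values, where chance alone would give about 21. Median UMIs per nucleus were high in oxygen male 2 (6687 in inhibitory, 6693 in excitatory and 2289.5 in non-neuronal nuclei, against at most 3804, 3797 and 1528 in the others) and in isoflurane female 3 (5058 in inhibitory and 5134 in excitatory nuclei, against at most 3703 and 3985). Isoflurane male 4 had a core level of 1779 CPM in inhibitory cluster 6, against 227 to 444 in the others, with 317 CPM of Egr1 (at most 125 in the others), 198 of Per1 (at most 75.6) and 238 of Junb (at most 89.2). These values of isoflurane male 4 rest on 13 nuclei with 20234 UMIs. In the same cluster oxygen male 2 had 23.1 CPM of Per1 (13.9 to 15.8) and oxygen female 4 had 43.0 of Nr4a1 (8.87 to 18.6). Oxygen male 2 had a core level of 126 CPM in inhibitory cluster 17 (99.6 to 106).

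In inhibitory nuclei oxygen male 4 had 7.16 CPM of Fosb (1.59 to 2.73 in the others), 22.5 of Nr4a1 (16.6 to 17.9) and 9.30 of Dusp1 (5.10 to 6.09), and oxygen female 2 had 14.6 of Nr4a1 (17.2 to 17.99). In excitatory nuclei oxygen female 4 had 26.1 CPM of Nr4a3 (14.0 to 17.4) and 36.4 of Ddx3x (39.7 to 40.4), and oxygen male 5 had 4.04 of Ier2 (0.774 to 1.54). Isoflurane female 1 had 21.5 CPM of Fos in inhibitory cluster 26 (51.7 to 57.2) and 1.96 in inhibitory cluster 13 (7.82 to 9.89). Isoflurane male 4 had 422 CPM of Cdk19 in pooled vascular nuclei (234 to 256 in the other 3). In non-neuronal nuclei oxygen male 3 had 426 CPM of Usp53 (231 to 278), 88.6 of Ddx3y (59.4 to 61.5) and 2.43 of Xist (0.366 to 0.795). Traces of Y-linked genes appeared in oxygen females: 0.162 CPM of Eif2s3y in female 2 and 0.350 of Uty in female 4 in excitatory nuclei, and 0.628 of Uty and 0.628 of Ddx3y in female 2 in non-neuronal nuclei, with 0 in the others. The effect differed between the sexes for 0 of 103 named genes (smallest edgeR adjusted p 0.989) and for 0 of 19 shares and levels (smallest adjusted permutation p 0.992).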

How the results depend on the processing

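Alternatives chosen after the data were seen were the striatal share as a covariate, the counts without the 3 libraries that hold over 25% of a cluster, the cluster counts without mixed-marker nuclei, and every alternative of the fits within clusters and in pooled vascular nuclei. Over 184 results, 4979 alternatives were computed, and among 3941 of single genes, lists and levels a called result turned its direction once. The nuclear oxidative phosphorylation list in inhibitory nuclei, lower with an adjusted p of 0.00135, stood higher without oxygen male 5 (adjusted p = 0.595, not past the threshold). With a mouse left out its adjusted p ran from 2.04e-07 to 0.595, and it lost its call without oxygen female 5 (0.0792), isoflurane female 5 (0.138) or isoflurane male 1 (0.189). Of the gene alternatives 2741 stayed on the same side of the threshold, 212 lost the call and 18 gained a call. For lists these were 688, 105 and 2. The counts on the same side include uncalled values that changed sign. In 107 alternatives a value that passed no test changed sign. The cause of the changes below was not tested unless stated.

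With DESeq2 in place of edgeR the genes changed numbered 57 in inhibitory (0 by edgeR), 3 in excitatory (1), 33 in non-neuronal (9) and 1 in mature oligodendrocyte-like nuclei (3). Without a filter there were 2 in excitatory nuclei, 70 in astrocyte-like (31), and 5 in mature oligodendrocyte-like nuclei. In the clusters there were then 2 in excitatory cluster 16 (1), 11 in inhibitory cluster 6 (7), 2 in inhibitory cluster 17 (0), 27 in inhibitory cluster 26 (9), 6 in inhibitory cluster 13 (3) and 2 in excitatory cluster 18 (0). A mean of at least 10 CPM gave 17 in non-neuronal nuclei, where fewer genes are tested. An additive model gave 2 in excitatory and 18 in non-neuronal nuclei, and equal nuclei per mouse, which lowers depth, gave 0 and 5. Without mixed-marker nuclei there were 0 in excitatory nuclei, 3 in non-neuronal nuclei and 0 in excitatory cluster 16, and 4 inhibitory (8) and 1 excitatory (3) clusters with a changed core level. Coarser clusters gave 1 excitatory cluster, and at least 25 nuclei per mouse gave 0, since excitatory clusters 16, 18 and 23 could then not be tested. With the striatal share as a covariate 7 genes passed in inhibitory nuclei.

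Without the 3 libraries that hold over 25% of a cluster there were 1 gene in inhibitory, 5 in non-neuronal and 1 in microglia-like nuclei, 2 in inhibitory cluster 26 and 5 inhibitory clusters with a changed core level. In the share of nuclei per deposited class, excitatory nuclei then passed as 1 of 3 (−3.60 percentage points, adjusted permutation p = 0.0340, against −1.51 with all mice). The rapid response list in inhibitory nuclei had an adjusted p of 0.138, and 8 more list calls were lost: 5 in inhibitory, 2 in excitatory and 1 in non-neuronal nuclei, each with its value in the report. That list had 0.656 with an estimated correlation and 0.620 by fry in 1 direction, and in non-neuronal nuclei 0.105 and 0.0756.

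With the replicate block, 0 genes passed in excitatory, 2 in non-neuronal, 10 in astrocyte-like, 7 in microglia-like and 16 in pooled vascular nuclei, 1 in inhibitory cluster 17 and 5 in inhibitory cluster 26, and 4 inhibitory clusters changed their core level (exact sign flips, smallest p 0.00195). Of the 3 excitatory clusters 2 passed, and the core rapid response level, excitatory cluster 18, lost its call (−1.46, adjusted exact sign-flip permutation p = 0.0807). Same-numbered mice do not pair: in each class 2 of 10 pairs correlated above 0.1 and 2 mice best with their own number, so the block is only a check. The sex difference was not fitted with it, since each block of sex and number holds mice of 1 sex. Of the named genes it ended the calls of Arhgef10l, Ccn1, Gm10138, Lrrc51, Prr14, Usp53 and Wipf3 in non-neuronal, AI849053, Gm27239, Megf9, Txnip and Wipf3 in astrocyte-like, 2900052L18Rik in mature oligodendrocyte-like, Narf in excitatory and Cdk19 in pooled vascular nuclei, and Pcsk1 in inhibitory cluster 26.

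Leaving out each mouse in turn gave 0 to 3 genes in inhibitory nuclei (3 without oxygen male 1, 1 without isoflurane female 5 or isoflurane male 3). It gave 0 to 2 in excitatory nuclei (2 without oxygen female 2, 4 or 5, and 0 without oxygen female 1, oxygen male 1, 2 or 3, or any isoflurane mouse but female 2 and male 4). In non-neuronal nuclei it gave 4 to 14 (14 without isoflurane male 5, 4 without oxygen female 3 or 4 or isoflurane male 1 or 2, and 5 without oxygen male 4 or isoflurane female 2 or 5). The range was 20 to 43 in astrocyte-like nuclei (20 without oxygen male 2) and 22 to 37 in pooled vascular nuclei. It was 1 to 5 in mature oligodendrocyte-like nuclei (5 without oxygen female 5, oxygen male 1 or isoflurane male 1, 1 without oxygen female 1, 3 or 4, oxygen male 2 or 4, isoflurane female 1 or 5 or isoflurane male 2). It was 1 to 3 in excitatory cluster 16 (3 without isoflurane female 4, 2 without oxygen male 3 or isoflurane male 3, 4 or 5) and 6 to 14 in inhibitory cluster 6 (14 without oxygen male 1). It was 0 to 1 in inhibitory cluster 17 (1 without oxygen female 1 or oxygen male 5), 5 to 16 in inhibitory cluster 26 (5 without isoflurane female 1, 16 without isoflurane female 3) and 2 to 5 in inhibitory cluster 13 (5 without oxygen female 5 or isoflurane male 2). Inhibitory clusters with a changed core level numbered 4 to 10 (4 without oxygen female 1 or 3 or isoflurane female 1, 3 or 5, and 5 without oxygen male 1 or 5 or isoflurane male 1, 4 or 5) and excitatory ones 2 to 4. Genes that differ between the sexes numbered 11 to 13 in inhibitory, 11 to 13 in excitatory and 6 to 7 in non-neuronal nuclei. The core level kept its direction and call with each mouse left out in inhibitory cluster 6 (1.54 to 1.91) and excitatory cluster 16 (1.69 to 1.88), and in pooled vascular nuclei (2.97 to 3.52). The adjusted p of the rapid response list ran from 0.000271 to 0.295 in inhibitory nuclei, from 2.14e-19 to 2.33e-09 in non-neuronal and from 0.178 to 0.858 in excitatory nuclei. In inhibitory nuclei it lost its call without oxygen female 3 (0.0816), oxygen male 4 (0.0885) or 5 (0.0774), isoflurane female 1 (0.0932), 3 (0.0814) or 5 (0.0593), or isoflurane male 1 (0.295), 4 (0.0671) or 5 (0.0822). The endothelial-like fit was not run. Of simulated genes changed 1.5 times edgeR recovered 48 of 66 in inhibitory, 49 of 66 in excitatory and 49 of 67 in non-neuronal nuclei, so changes of this size or smaller can be missed at this depth. No batch was named.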

Other observations

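The test of clusters that share Drd3 was chosen only after the result was seen, and the groups of clusters described here were put together then as well.

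Septal neuron-like clusters, fixed by their markers and numbering 7 over both neuronal classes, all had lower mean core rapid response levels under isoflurane. Inhibitory cluster 13 (log2 difference −0.76, adjusted permutation p = 0.00156), inhibitory cluster 3 (−0.53, 148 ± 63.4 to 98.7 ± 22.5 CPM, 0.0383) and excitatory cluster 23 (−0.86, 301 ± 91.4 to 181 ± 89.4 CPM, 0.0398) passed, with 0, 1 and 1 of 10 isoflurane mice above the oxygen median of their sex. Without mixed-marker nuclei only cluster 13 of these kept its call (−0.66), cluster 3 lost it (−0.41, adjusted permutation p = 0.184) and cluster 23 could not be tested. Excitatory cluster 14 (−0.68, adjusted permutation p = 0.0532), excitatory cluster 17 (−0.57, 0.185), inhibitory cluster 31 (−0.52, 0.140) and inhibitory cluster 20 (−0.33, 0.436) did not. Of the striatal projection neuron-like clusters, inhibitory cluster 6 was higher (+1.79, adjusted permutation p = 0.000651), while clusters 24 (+0.93, 0.127), 11 (+0.30, 0.388), 2 (−0.46, 0.0864) and 0 (−0.17, 0.472) did not pass and cluster 19 was not tested. The 2 Esr1 preoptic inhibitory neuron-like clusters, 16 and 22, had −0.02 and −0.15 (adjusted permutation p = 0.974 and 0.758).

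Over both gases, the share of nuclei with a core UMI at equal depth ran from 7.04% to 23.3% over the 11 named neuron types of the 2 classes. It was 23.3% in warm-sensitive preoptic excitatory neuron-like nuclei and 19.2% in magnocellular neuron-like nuclei, against 7.04% in Esr1 preoptic inhibitory neuron-like and 7.94% in cholinergic neuron-like nuclei, with median UMIs of 3707, 4601, 3942.5 and 4300. These shares pool nuclei of all mice and were not tested.

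Inhibitory cluster 6 has the dopamine receptor gene Drd3 among its 10 leading genes, as have inhibitory clusters 24 and 37. The hypothesis that clusters with Drd3 respond alike was tested on clusters 6 and 24, and cluster 37 had too few mice with enough nuclei. Cluster 24 (Rreb1, Ust and Drd3, 1214 nuclei) went from 223 ± 174 CPM in 9 oxygen mice to 367 ± 157 in 10 isoflurane mice (log2 difference +0.93, exact permutation p = 0.0369, the higher of both, adjusted over all clusters to 0.127), with all 10 isoflurane mice above the oxygen median of their sex. The direction is in line with the hypothesis, but cluster 24 fails the adjustment and the pair was noticed in the same data.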
